A study of Mus musculus with 12 samples.

How the data were processed

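RNA of 12 samples of CD45+CD11b+ cells, sorted by CD34 from mammary glands of mice on a low-fat or a high-fat diet, was amplified with a low-input protocol and counted on the NanoString nCounter mouse Fibrosis V2 panel. Glands were digested with collagenase for 1 hour and then with trypsin before sorting. The deposited table holds log2 values of 760 genes, normalized per sample by the authors. Each column was close to log2 of a whole number plus 1 constant for the sample. Values under 300 counts were whole within a tolerance of 0.02 in every sample. Of all values of a sample, 98.0% to 99.6% were whole within 0.1. What the constant was computed from is not given in the sources used here. Whole counts and total counts per sample were recovered from this structure. The authors' further tables hold, per the labels, gene-centred log2 values of selected genes for 4 comparisons, with a cluster number of another kind (unit other, the authors' own numbering), and they matched the centred values of the main table. Symbols were used as given: 748 matched the reference gene table, 9 matched a synonym and 3 had no match.

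Total counts ran from 78316 to 780070 per sample and set the precision of low values, and counting error does not include amplification, since amplified molecules are not independent. The filter kept 594 genes with a linear value of at least 20 in at least 3 samples, and 166 genes were left out. Log2 values were used as deposited, with no further normalization. Groups of diet and population came from the labels, with 3 samples in each of 4 groups. A single linear model with 4 group means was fitted in limma 3.58.1 under R 4.3.3, with statmod 1.5.0, with moderated statistics and a mean-variance trend. Contrasts were CD34- minus CD34+ cells on each diet, high-fat minus low-fat diet in each population, and the difference between the former 2. All tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 passed. Differences are log2 values ± SE from this model, and group values are means ± SD of log2 values. Beside a gene, the last number in brackets is its adjusted p, and beside a list the number before that with an estimated correlation is camera's adjusted p at the preset correlation. An exact permutation test of 3 against 3 samples cannot give a p below 0.1, so none was used per gene.

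Lists of 16 pathways and 12 cell types were fixed from general knowledge, and the 23 lists with at least 4 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The other 5 lists had fewer tested members and were not tested as sets. Camera was also run with an estimated correlation, under which 0 lists passed in any comparison against 11, 8, 10 and 10 at the preset one in the order high-fat, low-fat, CD34+ and CD34-. Fry, which asks whether a list's genes move on balance one way without comparing them with other genes, called 5, 11, 0 and 11.

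The named genes of each comparison were the 12 with the largest log2 difference in each direction among those that passed. For each list up to 4 passing members with the largest differences were taken, or, where none passed, up to 2 with the smallest p. The 3 genes with the smallest p were named for the interaction, and Cd34 and Ptprc always. Some genes that the rule takes are left out of the text with their results. Names outside this rule were chosen after their values were seen. They are Cpa3, Cd6, Acta2, Cxcl12, Adipoq, Tgfbr2, Ski and some of the interaction genes found with the mouse as a block. The model, filter, lists, named-gene rule and most alternative settings were chosen before the data were examined. Voom, the filter on recovered counts, the 2 libraries left out together and the mouse block with re-centring were added afterwards.

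Numbers of samples were checked as a sign of shared mice by correlating deviations from the group means across genes. Each of the 6 samples of the high-fat diet and each of the 6 of the low-fat diet correlated most with the sample of its own number in the other population. Between diets this held for 0 of 6 samples in CD34+ cells and 2 of 6 in CD34- cells. The mouse was therefore used as a block for population comparisons, as an alternative, with a consensus within-mouse correlation of 0.448. No 2 samples of a group were copies of one library, with a chi-square per degree of freedom of 13.3 or more between replicates.

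The model was tested on simulated data with 200 changed genes in each of 20 runs. It recovered 90.0%, 90.8%, 89.3% and 88.8% of genes with a log2 change of 2 in the 4 comparisons in the same order and 69.9% for the interaction. False calls were 3.84% or less of calls. At a log2 change of 1 it recovered 52.0%, 53.5%, 49.8%, 50.4% and 26.9%. Simulated values were drawn independently, with no correlation between genes or within mice, and more genes were changed than were called in the data. The rates of recovery and false calls hold for such values and need not hold for the data.

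Alternatives covered pseudocounts of 10 and 20, no filter and a stricter filter, values under 20 set to 20, re-centring on the median, quantile normalization, no mean-variance trend, sample quality weights, the mouse or replicate number as a block, only the 6 samples compared, a plain test per gene, camera with an estimated correlation, voom on recovered counts, a filter on recovered counts, 2 libraries left out together, and each replicate left out in turn. Rescaling on the panel's reference genes was not run, because these genes were not analysed here.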

Results

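The NanoString nCounter mouse Fibrosis V2 panel, which counts target RNAs with barcoded probes, measured 760 genes in 12 samples of white blood cells from mammary glands. Female FVB/N mice ate a low-fat or a high-fat diet for 16 weeks from 3 weeks of age, with 3 mice per diet. Live CD45+ cells carrying CD11b, a myeloid surface protein, were sorted by CD34, a protein of progenitor cells. The labels call the CD11b+CD34+ cells myeloid progenitors and the CD11b+CD34- cells monocytes and macrophages. The 4 groups of diet and population held 3 samples each. The series asked how obesity changes gene expression in these cells.

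Recovered total counts ranged from 78316 to 780070 per sample, a ratio of 9.96. On the low-fat diet, replicates 1, 2 and 3 held 457817, 404179 and 78316 counts in CD34- cells and 313528, 157361 and 406892 counts in CD34+ cells. On the high-fat diet they held 385629, 223701 and 535463 counts in CD34- cells and 400322, 532744 and 780070 counts in CD34+ cells. The 10 most abundant genes took 30.8% to 50.2% of the counts of a sample. The first principal component held 43.6% of the variance and separated the populations, and the second held 19.6%. Samples of the same number within a diet resembled each other, as samples of one mouse would, and numbers did not match across diets. Correlations across genes of their deviations from the group means were 0.306 to 0.434 for same-numbered samples of a diet and -0.375 to 0.143 for the others.

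**Figure D1:**
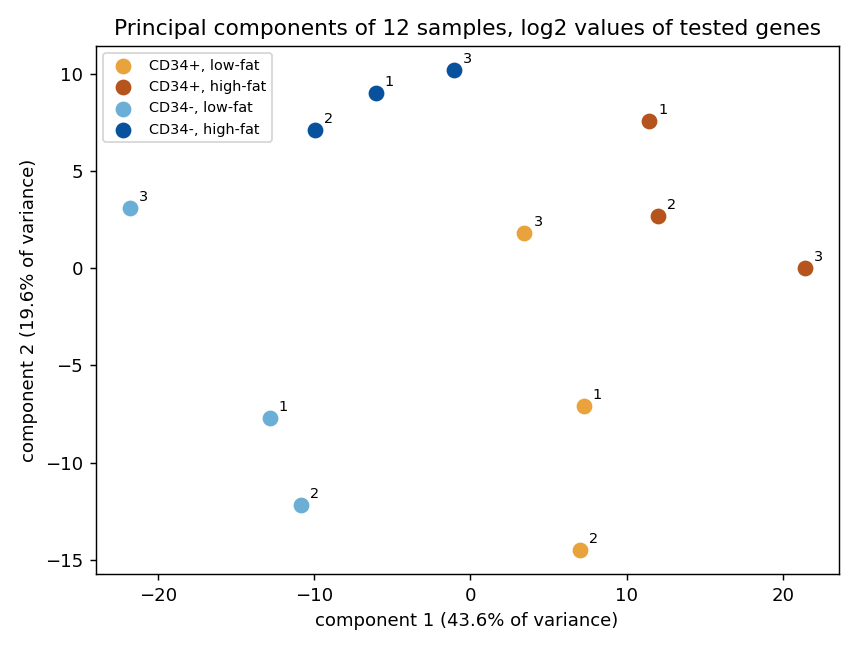
Scores of the 12 samples on principal components 1 and 2 of the log2 values of 594 genes, with the variance of each component in percent on its axis. CD34- samples lie below 0 on component 1 (-21.8 to -1.04) and CD34+ samples above 0 (3.46 to 21.4).

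Cd34, the gene of the sort marker, differed between the populations past the threshold on the low-fat diet and not on the high-fat diet. On the low-fat diet it was lower in CD34- than in CD34+ cells by a log2 difference of -1.68 ± 0.49 (SE, n = 3 per group, adjusted p = 0.0475), with group means of 3.85 ± 0.87 and 5.53 ± 0.49 (SD). On the high-fat diet the difference was -0.34 ± 0.49 (adjusted p = 0.707), with means of 5.27 ± 0.13 and 5.61 ± 0.72. Cd34 counts were low, at 34, 27 and 2 in the low-fat CD34- samples. Ptprc, the gene of CD45, had a mean log2 value of 10.98 or more in each of the 4 groups, and Itgam, the gene of CD11b, was not analysed here. On the high-fat diet Ptprc was higher in CD34- than in CD34+ cells by 0.87 (limma adjusted p = 0.0209). With the mouse as a block, Ptprc was higher there (adjusted p = 0.000432) and also on the low-fat diet, by 0.42 (0.0488). In the same fit Cd34 was lower in CD34- cells on the low-fat diet (-1.68 ± 0.47, adjusted p = 0.0155) and did not pass on the high-fat diet. In the fit with no block, the low-fat call for Cd34 ended without any one of CD34- replicates 1, 2 and 3 or CD34+ replicates 1 and 3 (adjusted p 0.059, 0.061, 0.134, 0.161 and 0.108). The high-fat difference became 0.07 without CD34+ replicate 2.

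The comparison of CD34- with CD34+ cells on the high-fat diet asked how the sorted populations differed in obese mice. Of 20 T and NK cell genes 14 were higher in CD34- cells, and of 7 collagen genes 2 were lower (adjusted p = 0.235 for each list with an estimated correlation). Gzma, which encodes a granzyme of killer cells, was 21.2-fold higher (log2 4.41 ± 0.78 SE, n = 3 per group, adjusted p = 0.0131), at 10.13 ± 0.40 (SD) against 5.73 ± 1.59. Col3a1, which encodes a fibrillar collagen, had a log2 difference of -2.59 ± 0.58 (adjusted p = 0.0214), at 6.63 ± 0.53 against 9.22 ± 1.44. In all, 41 genes were higher and 12 lower among 594 tested, each in the same direction in the 3 same-numbered pairs.

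In the T and NK cell list, 18 of 20 genes were higher adjusted over the list alone, with a median log2 difference of 2.37 (camera adjusted p = 3.9e-11 and adjusted p = 0.235 with an estimated correlation). The 14 included Gzmb (3.84 ± 0.90, adjusted p = 0.0246), Nkg7 (3.79 ± 0.69, 0.0131), Eomes, a transcription factor of cytotoxic cells (3.55 ± 0.86, 0.0268), and the T cell receptor component Cd3e (2.70 ± 0.67, 0.0292). Ncr1, an activating receptor of NK cells, differed by 3.37 ± 0.81 (0.0264), with 17, 10 and 8 counts in the CD34+ samples. Outside the lists, the interferon gamma gene Ifng differed by 3.26 ± 0.63 (0.0151) and the chemokine gene Xcl1 by 3.35 ± 0.64 (0.0151). Of 5 B cell genes 2 were higher, among them Blk (2.90 ± 0.81, 0.0413; 4 adjusted over the list alone; median 2.11, adjusted p = 0.0154 and adjusted p = 0.355 with an estimated correlation). Of 4 neutrophil genes, Fpr1 (1.96 ± 0.45, 0.0244) and Csf3r (1.48 ± 0.41, 0.0413) were higher (3 adjusted over the list alone and adjusted p = 0.0135 and adjusted p = 0.281 with an estimated correlation).

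The 2 collagen genes that were lower in CD34- cells (7 adjusted over the list alone) were Col1a2, at -2.92 ± 0.80 (adjusted p = 0.0413), and Col3a1, and the list had a median of -1.82 (camera adjusted p = 2.7e-06 and adjusted p = 0.235 with an estimated correlation). The fibroblast list, which holds several of the same collagens, had 2 of 9 genes lower (5 adjusted over the list alone) and a median of -1.63 (1.82e-05 and adjusted p = 0.235 with an estimated correlation). Without high-fat CD34+ replicate 2, in which matrix genes were high, Col1a2 was at -1.765 ± 0.574 (0.0611) and Col3a1 at -1.757 ± 0.428 (0.0232), and the collagen and fibroblast medians were -0.90 and -0.82 with 1 gene lower in each (camera adjusted p = 0.000671 and 0.00582). Of 15 protease and inhibitor genes 2 were lower, among them the protease inhibitor gene Timp2 (-1.30 ± 0.36, 0.0413; 3 adjusted over the list alone; 6.22e-05 and adjusted p = 0.235 with an estimated correlation). Of 20 lipid genes 3 were lower (3 adjusted over the list alone), Lpl, the lipoprotein lipase gene (-2.40 ± 0.53, 0.0214), Fabp5 (-1.23 ± 0.35, 0.0477) and Lipa (-1.03 ± 0.30, 0.0479), and the list as a whole was not called (median 0.15, 0.221). The growth factor gene Igf1 differed by -2.24 ± 0.61 (0.0413), the receptor gene Axl by -1.48 ± 0.29 (0.0151) and Cxcl1, the only inflammatory gene of 20 to pass, by -1.69 ± 0.49 (0.0479). The inflammatory list (0 adjusted over the list alone, 6 of 20 at an unadjusted p under 0.05) had a median of -0.46 (9.38e-05 and adjusted p = 0.235 with an estimated correlation). In the macrophage, complement, matrix glycoprotein and alternative activation lists limma called 0 genes (0, 3, 0 and 0 adjusted over the list alone), while 4 of 5, 3 of 4, 2 of 11 and 2 of 6 were lower at an unadjusted p under 0.05 and 4, 2, 2 and 2 with the mouse as a block. Their medians were -0.87 (0.00672 and adjusted p = 0.235 with an estimated correlation), -1.60 (0.0173 and adjusted p = 0.235 with an estimated correlation), -0.78 (0.00672 and adjusted p = 0.355 with an estimated correlation) and -0.52 (0.0371 and adjusted p = 0.355 with an estimated correlation). C3ar1, a complement receptor gene, differed by -1.83 (adjusted p = 0.0543) and passed with the mouse as a block (adjusted p = 4.07e-05). Without high-fat CD34+ replicate 2 the complement and matrix glycoprotein medians were -0.93 (camera adjusted p = 0.107) and -0.23 (0.244), and Timp2 was at -1.28 (0.059) and Csf3r at 1.37 (0.0719). In that fit 5 of 20 inflammatory genes were lower (median -0.694, camera adjusted p = 1.65e-06), 2 of 5 macrophage genes and 1 of 4 complement genes were lower, 3 of 5 B cell genes and 1 of 4 neutrophil genes were higher, and the alternative activation median was -0.825 (0.0263). With this library left out, camera was run at the preset correlation only.

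**Figure D2:**
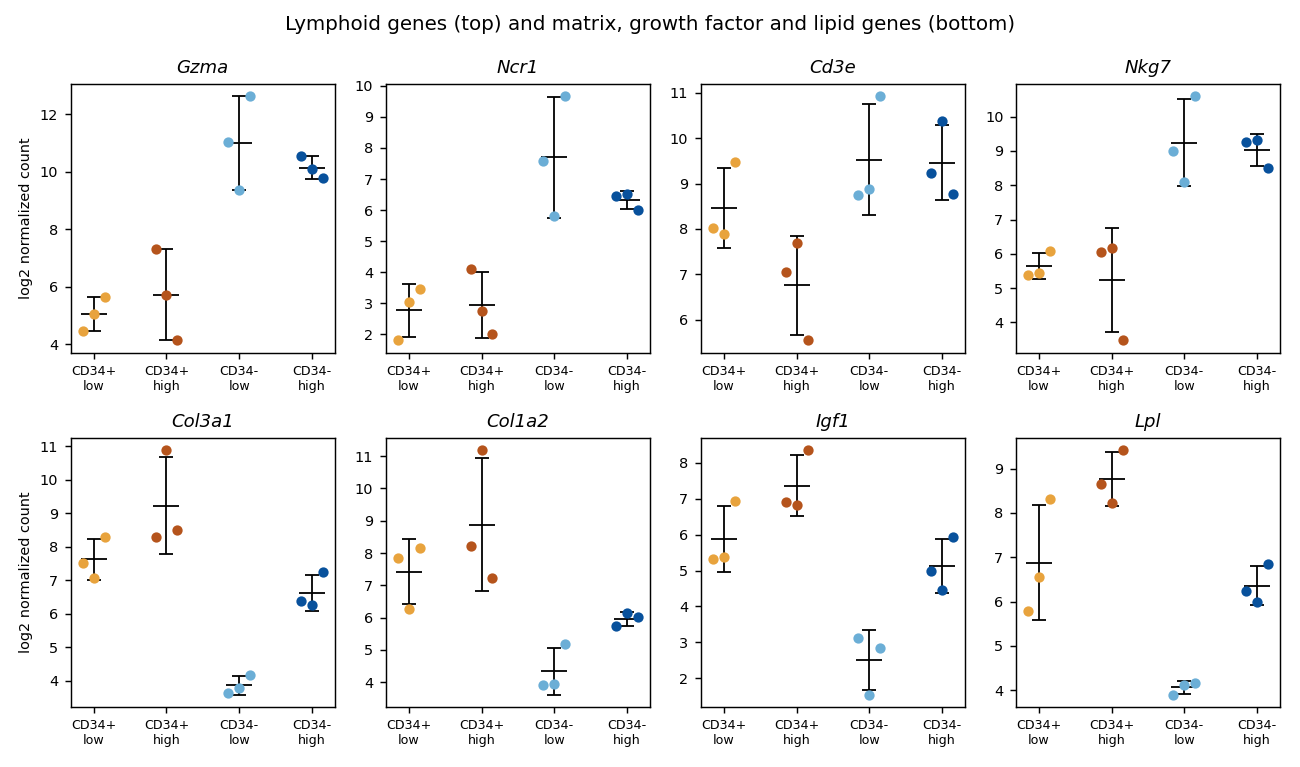
Log2 values of 8 genes in each of the 12 samples, by diet and sorted population, with points for samples and lines for the mean and SD of 3. Gzma, Ncr1, Cd3e and Nkg7 were higher in CD34- cells on the high-fat diet (log2 differences 4.41, 3.37, 2.70 and 3.79) and Col3a1, Col1a2, Igf1 and Lpl lower (-2.59, -2.92, -2.24 and -2.40).

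With the mouse as a block, 149 genes passed (98 higher, 51 lower), including the same 53. They held 4 collagen, 4 fibroblast and 8 inflammatory genes that were lower, and 7 protease and inhibitor genes lower and 2 higher. Higher were also 19 T and NK cell, 4 B cell and 4 neutrophil genes. The median log2 difference of all genes was 0.22, and re-centring each sample without the block gave 43 genes higher and 35 lower (55.1% higher against 77.4%). Quantile normalization gave 39 and 23. With the block and re-centring together, 61 genes were higher and 80 lower (43.3% higher against 65.8% with the block alone). The same 53 genes passed in that fit too. The balance of higher to lower calls thus depended on the scaling. Without CD34- replicate 1, CD34- replicate 2 or CD34+ replicate 3, limma called 0, 1 and 5 genes, and with all samples 140 had an unadjusted p under 0.05 and 3 passed a plain adjusted test. Without high-fat CD34+ replicate 2, which was high in matrix genes, and low-fat CD34- replicate 3, the shallowest library, 91 passed.

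The same comparison on the low-fat diet asked how the populations differed in lean mice. Of 20 T and NK cell genes 8 were higher in CD34- cells, and 4 of 7 collagen genes and 5 of 20 inflammatory genes were lower (adjusted p = 0.347 for each list with an estimated correlation). Gzma was 62.0-fold higher (log2 5.95 ± 0.78 SE, n = 3 per group, adjusted p = 0.000821), at 11.01 ± 1.63 (SD) against 5.05 ± 0.58. Ccr7, a chemokine receptor gene of migrating dendritic cells and lymphocytes, differed by -1.55 ± 0.22 (adjusted p = 0.00119), and Cd163, a scavenger receptor gene of macrophages, by -2.53 ± 0.39 (0.00156). In all, 16 genes were higher and 42 lower of 594, each in the same direction in the 3 same-numbered pairs.

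In the T and NK cell list, 9 of 20 genes were higher adjusted over the list alone (median 1.09, camera adjusted p = 8.32e-13 and adjusted p = 0.347 with an estimated correlation). Gzmb differed by 5.19 ± 0.90 (adjusted p = 0.00303), Ncr1 by 4.92 ± 0.81 (0.00217), and the perforin gene Prf1 by 3.72 ± 0.74 (0.00606), and outside the lists Xcl1 differed by 4.21 ± 0.64 (0.00156) and Ifng by 2.35 ± 0.63 (0.0299). The neutrophil genes Mmp8 (2.84 ± 0.80, 0.0361) and Csf3r (1.49 ± 0.41, 0.0316) were 2 of 4 to pass (2 adjusted over the list alone; median 1.41, 0.00294 and adjusted p = 0.347 with an estimated correlation). Of 5 B cell genes limma called 0 (1 adjusted over the list alone, 2 at an unadjusted p under 0.05), with a median of 1.20 (0.0377 and adjusted p = 0.42 with an estimated correlation).

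Of 7 collagen genes, 4 were lower (5 adjusted over the list alone; median -2.16, 0.000425 and adjusted p = 0.347 with an estimated correlation): Col3a1 (-3.75 ± 0.58, 0.00156), Col1a2 (-3.09 ± 0.80, 0.0266), Col5a1 (-2.37 ± 0.57, 0.0199) and Col4a2 (-2.16 ± 0.40, 0.00461). The fibroblast list shared several of these, with 3 of 9 lower (6 adjusted over the list alone; median -1.71, 0.000932 and adjusted p = 0.347 with an estimated correlation). Of 20 inflammatory genes, 5 were lower (9 adjusted over the list alone). The list had a median of -0.83 (camera adjusted p = 0.00105 and adjusted p = 0.347 with an estimated correlation). Among the 5 were the chemokine genes Ccl2 (-3.06 ± 0.75, 0.0217), Cxcl1 (-2.55 ± 0.49, 0.00538) and Cxcl16 (-1.16 ± 0.30, 0.0271). In pairs 1, 2 and 3 Ccl2 differed by -2.03, -1.44 and -5.69, so its mean rests largely on pair 3, which holds the shallowest library. Cd163 was the only one of 5 macrophage genes to pass (1 adjusted over the list alone; median -0.79, 0.0223 and adjusted p = 0.347 with an estimated correlation). Mmp8 was higher and Mmp14 (-1.51 ± 0.40, 0.0294) lower among 15 protease genes (1 and 7 adjusted over the list alone; median -0.91, 0.0432 and adjusted p = 0.347 with an estimated correlation). Igf1 (-3.37 ± 0.61, 0.00408), Lpl (-2.81 ± 0.53, 0.00538) and Fabp5 (-2.25 ± 0.35, 0.00156) were lower as well, and the low-fat CD34- samples held 14, 4 and 2 counts of Igf1. The 2 diets shared 14 genes higher in CD34- cells and 9 lower, where 1.10 and 0.848 would be shared if calls were independent, and 0 genes were called in opposite directions by limma. Log2 differences on the 2 diets had a Pearson r of 0.822 and a Spearman rho of 0.677 across 594 genes, which are not independent replicates.

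With the mouse as a block, 149 genes passed (47 higher, 102 lower), including the same 58. They held 14 T and NK cell genes and 3 B cell genes that were higher, and 13 inflammatory, 9 protease and inhibitor, 6 fibroblast and 4 macrophage genes that were lower. The median of all genes was -0.14, and re-centring gave 24 higher and 34 lower (41.4% higher against 27.6%; quantile normalization 26 and 31). Without CD34- replicate 1, CD34- replicate 2 or CD34+ replicate 1, 33, 37 and 26 genes passed. Without CD34+ replicate 3, in which the mast cell genes Cpa3 and Tpsb2 stood at 9.30 and 9.39 on the log2 scale, 5 lists were called.

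The diet comparison in CD34+ cells asked how obesity changed the cells labelled progenitors. Of 20 inflammatory genes 4 rose (adjusted p = 0.336 for the list with an estimated correlation), as did Timp1 and 5 further genes, and 4 genes fell, among them Il21r, Ccr7 and Irf1. Timp1, which encodes a metalloprotease inhibitor, rose by a log2 change of 3.24 ± 0.66 (SE, n = 3 per group, adjusted p = 0.0345), from 3.98 ± 0.44 (SD) to 7.22 ± 1.41. The size of this change is uncertain, as the low-fat samples held 19, 6 and 18 counts of Timp1. The cytokine gene Il6 rose by 2.17 ± 0.42 (adjusted p = 0.0281), from 7.77 ± 0.64 to 9.95 ± 0.61. Il21r, the receptor gene of interleukin 21, changed by -2.05 ± 0.37 (0.0281), from 9.24 ± 0.33 to 7.19 ± 0.43. Of 594 genes, 10 rose and 4 fell.

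Of 20 inflammatory genes 4 rose (8 adjusted over the list alone; median 0.69, camera adjusted p = 0.000699 and adjusted p = 0.336 with an estimated correlation): Cxcl2 (2.44 ± 0.56, adjusted p = 0.0409), Il10 (2.31 ± 0.49, 0.0345), Il6 and Cxcl1 (2.11 ± 0.49, 0.0409). Il10 encodes an anti-inflammatory cytokine, unlike the others. Cd14, a receptor gene for bacterial lipopolysaccharide, was the 1 of 5 macrophage genes to rise (1.70 ± 0.39, 0.0409; 4 adjusted over the list alone; list 0.00397 and adjusted p = 0.336 with an estimated correlation). Col4a2, of basement membrane collagen, rose by 1.86 ± 0.40 (0.0345) as the only one of 7 collagen genes to pass (3 adjusted over the list alone; median 1.46, 0.000845 and adjusted p = 0.343 with an estimated correlation). Timp1 was the only one of 15 protease and inhibitor genes to pass (2 adjusted over the list alone; 0.00517 and adjusted p = 0.336 with an estimated correlation). Fabp4, a fatty acid carrier of fat cells and macrophages, rose by 1.89 ± 0.43 (0.0409), as 1 of 4 fat cell genes (3 adjusted over the list alone; median 1.77, 0.0178 and adjusted p = 0.336 with an estimated correlation). The heme oxygenase gene Hmox1 rose by 2.02 ± 0.43 (0.0345) and the interferon-induced Oasl1 by 3.55 ± 0.84 (0.0412), from 14, 2 and 21 counts in the low-fat samples. Ccr7 (-1.13 ± 0.22, 0.0281) and the interferon regulator Irf1 (-1.09 ± 0.26, 0.0412) fell.

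Limma called 0 genes of the matrix glycoprotein, alternative activation, fibroblast, B cell and T and NK cell lists in CD34+ cells (3, 2, 0, 3 and 0 adjusted over the list alone), while 6 of 11, 2 of 6 and 3 of 9 were higher and 3 of 5 and 7 of 20 lower at an unadjusted p under 0.05. The medians were 1.15 (camera adjusted p = 0.000845 and adjusted p = 0.336 with an estimated correlation), 1.03 (0.0145 and adjusted p = 0.336 with an estimated correlation), 1.34 (0.0178 and adjusted p = 0.545 with an estimated correlation), -1.17 (0.0146 and adjusted p = 0.453 with an estimated correlation) and -0.55 (0.0145 and adjusted p = 0.545 with an estimated correlation). Fn1 (2.03, 0.0652) and Col3a1 (1.60, 0.168) did not pass, and Col1a2 reached 11.2 and Col3a1 10.9 on the log2 scale in replicate 2 of the high-fat CD34+ samples. Without that library Col4a2 was at 1.555 ± 0.432 (adjusted p = 0.0539), and the collagen, matrix glycoprotein and fibroblast medians were 0.60, 0.61 and 0.31 (camera adjusted p = 0.105, 0.0918 and 0.556). In that fit 2 of 20 T and NK cell genes and 1 of 5 B cell genes were lower, with medians of -0.922 (0.00403) and -1.565 (0.00943), and 6 of 20 inflammatory genes and 2 of 5 macrophage genes were higher. Camera was run at the preset correlation only with this library left out. Re-centring gave 12 genes higher and 1 lower (92.3% higher against 71.4%). Limma called 0 genes without any one of low-fat CD34+ replicates 1 and 2 or high-fat CD34+ replicates 1 and 3, and with all samples 104 had an unadjusted p under 0.05 and 0 passed a plain adjusted test (65 unadjusted). In turn 29 passed without high-fat CD34+ replicate 2 and 54 without it and low-fat CD34- replicate 3.

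The diet comparison in CD34- cells asked the same of the cells labelled monocytes and macrophages. All 30 genes that passed rose, among them genes of the inflammatory, collagen, fat cell and macrophage lists. Fabp4 rose 6.71-fold (log2 2.75 ± 0.43 SE, n = 3 per group, adjusted p = 0.0049), from 7.11 ± 0.75 (SD) to 9.86 ± 0.35. Cxcl1, a neutrophil attractant, rose 7.83-fold (2.97 ± 0.49, adjusted p = 0.0049), and Csf1r, the receptor gene of the macrophage growth factor, rose by 1.43 ± 0.28 (0.0119).

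Of 20 inflammatory genes 4 rose (12 adjusted over the list alone; median 0.97, camera adjusted p = 0.00012 and adjusted p = 0.292 with an estimated correlation): Cxcl1, Cxcl2 (2.64 ± 0.56, adjusted p = 0.0173), Il6 (2.21 ± 0.42, 0.0119) and Il10 (2.18 ± 0.49, 0.0198). Of 5 macrophage genes Cd14 (1.71 ± 0.39, 0.0209), Cd163 (1.55 ± 0.39, 0.0337) and Csf1r rose (5 adjusted over the list alone; median 1.43, 0.00132 and adjusted p = 0.292 with an estimated correlation). Of 6 genes of alternative macrophage activation, the fibronectin gene Fn1 (2.63 ± 0.54, 0.0172), the lipid regulator Pparg (1.93 ± 0.41, 0.018) and Cd163 rose (4 adjusted over the list alone; median 1.38, 0.00377 and adjusted p = 0.292 with an estimated correlation). Fabp4, Pparg and Lpl (2.29 ± 0.53, 0.0221) were 3 of 4 fat cell genes to rise (3 adjusted over the list alone; median 2.11, 0.00193 and adjusted p = 0.263 with an estimated correlation), and macrophages express these as well. Col4a2 (2.99 ± 0.40, 0.00209) and Col3a1 (2.76 ± 0.58, 0.0172) rose among 7 collagen genes (4 adjusted over the list alone; median 1.63, 0.00377 and adjusted p = 0.4 with an estimated correlation), and Col3a1 alone among 9 fibroblast genes (2 adjusted over the list alone; 0.0474 and adjusted p = 0.501 with an estimated correlation). Flt1, a receptor gene of vascular growth factor, rose by 1.56 ± 0.37 (0.0267) as 1 of 6 endothelial genes (5 adjusted over the list alone; median 1.54, 0.0171 and adjusted p = 0.292 with an estimated correlation). Timp1 (3.00 ± 0.66, 0.0196), Hmox1 (2.66 ± 0.43, 0.0049), Igf1 (2.62 ± 0.61, 0.0221) and the Fc receptor gene Fcgr4 (1.81 ± 0.35, 0.0119) also rose. Timp1 had 18, 20 and 1 counts and Col4a2 17, 8 and 2 in the low-fat CD34- samples.

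**Figure D3:**
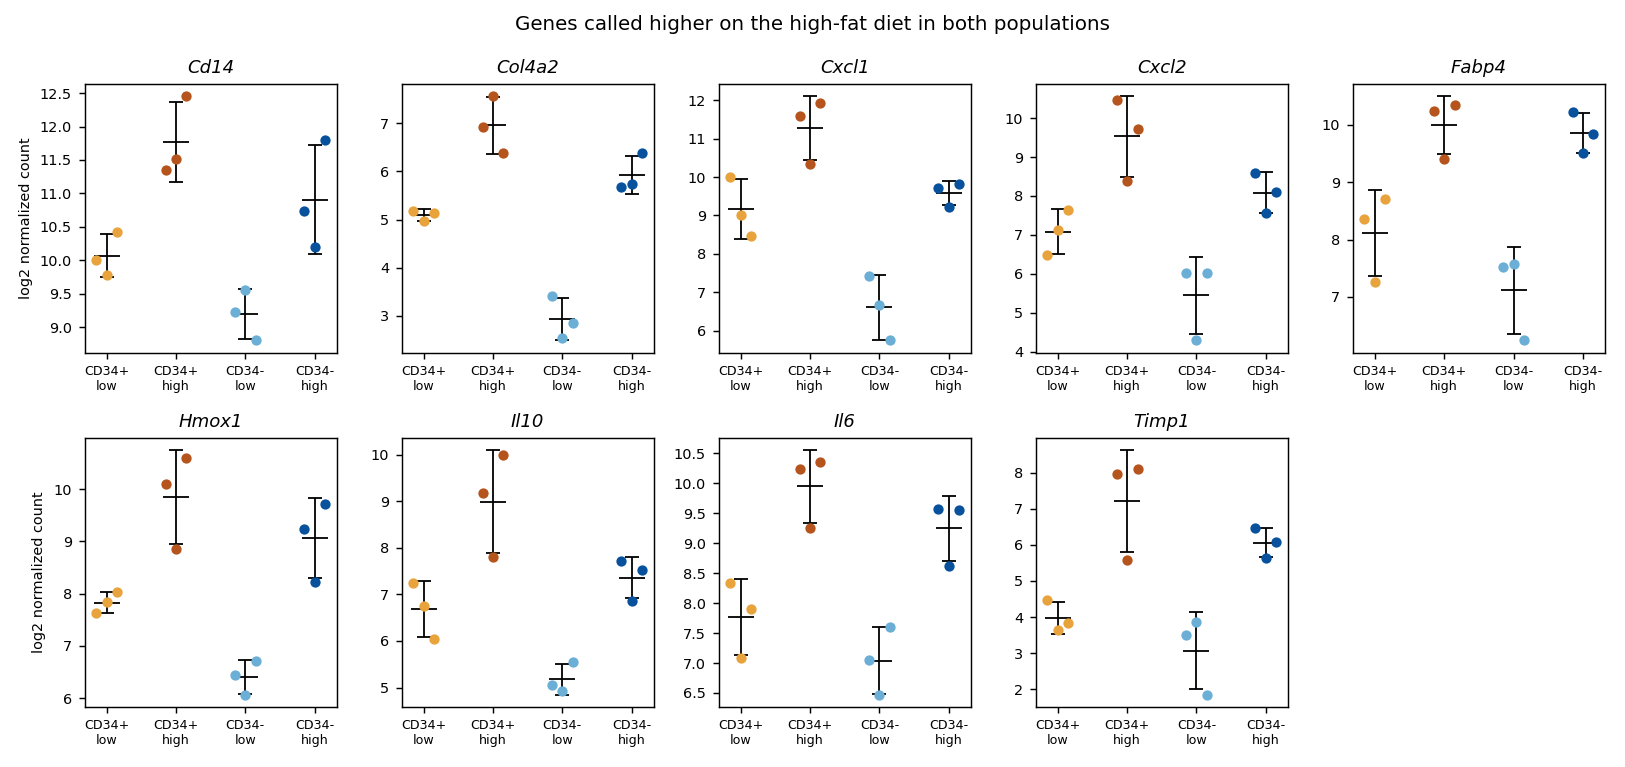
Log2 values of the 9 genes that rose on the high-fat diet in both populations, in each of the 12 samples by diet and population, with points for samples and lines for the mean and SD of 3. The log2 rise ran from 1.70 (Cd14) to 3.24 (Timp1) in CD34+ cells and from 1.71 (Cd14) to 3.00 (Timp1) in CD34- cells.

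Limma called 0 genes of the T and NK cell, B cell and antigen presentation lists for diet in CD34- cells (0 of each adjusted over the list alone), with 1 of 20 lower, 0 of 5 and 1 of 13 higher at an unadjusted p under 0.05. Against a median rise of 0.35 over all genes, their medians were -0.14 (camera adjusted p = 0.000177 and adjusted p = 0.433 with an estimated correlation), -0.51 (0.01 and adjusted p = 0.399 with an estimated correlation) and -0.10 with a mean of 0.01 and a test below the other genes (0.0169 and adjusted p = 0.292 with an estimated correlation). The diet changes of both populations shared 9 genes that rose, Cd14, Col4a2, Cxcl1, Cxcl2, Fabp4, Hmox1, Il10, Il6 and Timp1, where 0.505 would be shared if calls were independent. Both populations came from the same mice, so these comparisons are not independent of each other. Re-centring gave 17 genes higher and quantile normalization 12 higher and 1 lower, and 49 passed without low-fat CD34- replicate 3 and high-fat CD34+ replicate 2. Without low-fat CD34- replicate 1, low-fat CD34- replicate 2, high-fat CD34- replicate 1 or high-fat CD34- replicate 3, 12, 4, 6 and 5 genes passed.

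**Figure D4:**
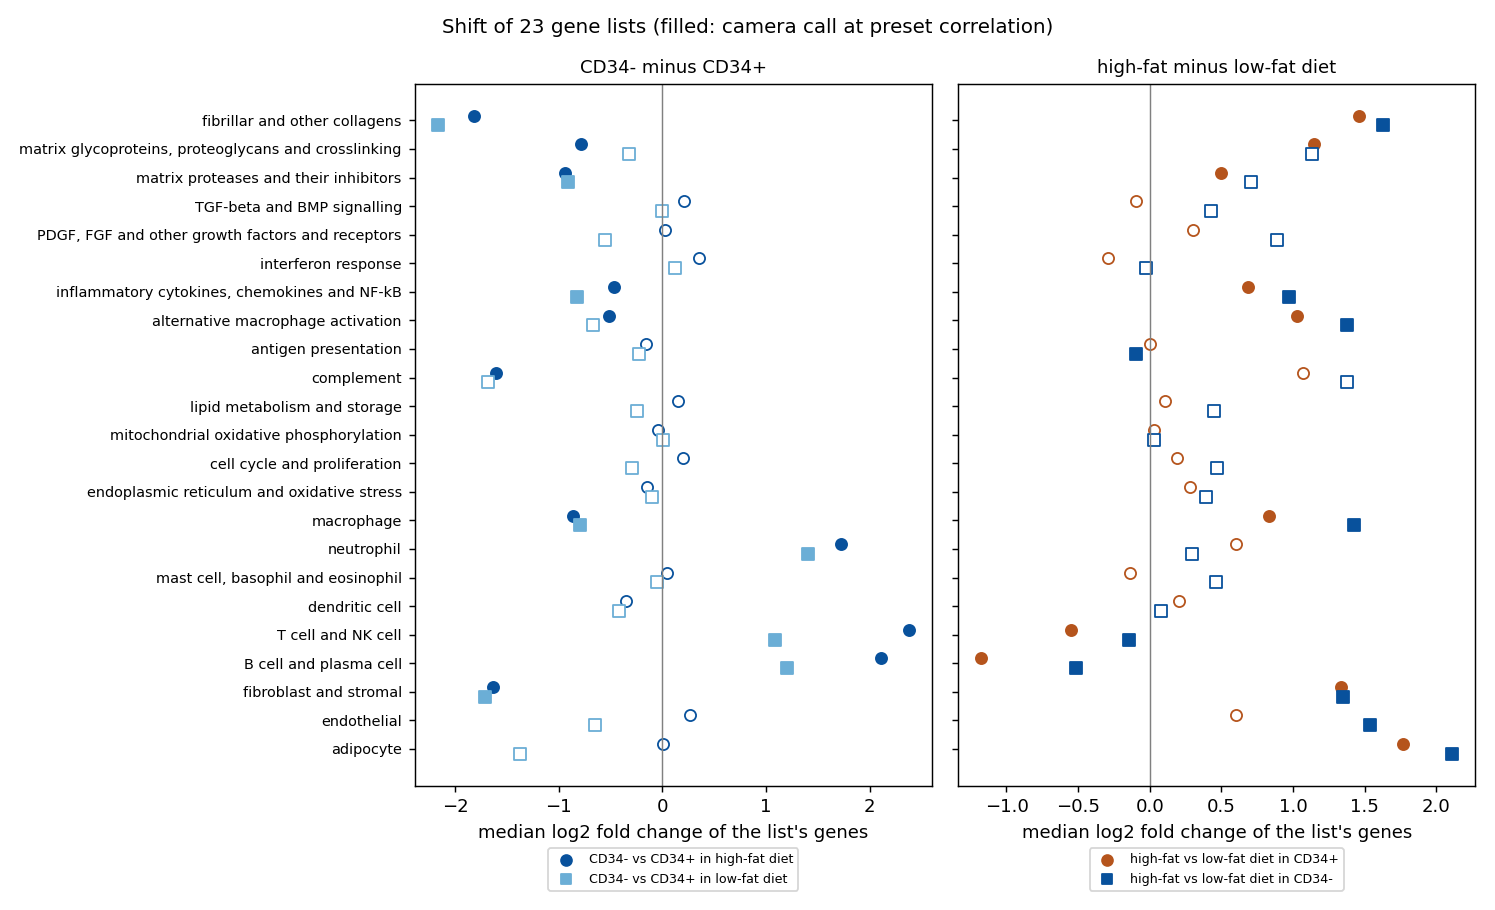
Median log2 difference of the tested members of each of 23 gene lists in the 4 comparisons, with filled symbols for lists called by camera at the preset correlation. The T and NK cell list lies at 2.37 and 1.09 in the population comparisons, and the collagen list at -1.82 and -2.16 there and at 1.46 and 1.63 in the diet comparisons; no call held with an estimated correlation.

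Whether the population difference depended on diet was tested directly. Limma called 0 of 594 genes, with 52 at an unadjusted p under 0.05 where 29.7 are expected by chance, and camera called 0 of 23 lists. A plain least-squares test gave 57 genes unadjusted and 0 adjusted, and voom gave 0. Il21r had the smallest p, with an interaction of 2.19 ± 0.52 on the log2 scale (adjusted p = 0.267). Nrp2, a receptor gene for semaphorins, had 1.41 ± 0.33 (0.267), and the NF-kB kinase gene Ikbkb 1.35 ± 0.34 (0.334). With the mouse as a block 9 genes passed, including Il21r (adjusted p = 0.0102) and Nrp2 (0.0169), all with a more positive difference on the high-fat diet. With the block and re-centring together 0 passed (smallest adjusted p = 0.0954), and 54 genes against 117 had an unadjusted p under 0.05. The median interaction of all genes was 0.36 before and 0.03 after re-centring, that of the 9 genes was 1.371 (median SE 0.292) and 1.041 (0.285), and Il21r stood at 1.864 ± 0.355.

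The authors' tables of selected genes hold 135 genes for CD34- against CD34+ cells on the high-fat diet, 31 on the low-fat diet, 7 for diet in CD34+ cells and 117 for diet in CD34- cells. How those genes were chosen is not given in the sources used here. Among them 49, 25, 4 and 30 passed here, and 4, 33, 10 and 0 genes that passed here were outside the tables. The 7 genes of the CD34+ diet table were all lower on the high-fat diet, while 10 of the 14 genes called here were higher. That table held genes of cluster 2 only, while each other table held 2 clusters, so the 2 sets of genes may not be alike in scope. Differences computed from the tables and from the fit here had opposite signs for 0 genes, as both rest on the same values.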

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

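The tests of the 3 patterns weighed below and the mouse block with re-centring were chosen after the results were seen, while the counts over other splits of the samples were set out beforehand.

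With the mouse as a block, the difference between CD34- and CD34+ cells depended on diet for 9 genes by the interaction test, each more positive on the high-fat diet. Among them, the interactions were 1.486 (adjusted p = 0.0169) for Cd3d, 1.641 (0.0169) for Cd3e, 1.371 (0.0336) for Cd3g and 2.194 (0.0102) for Il21r on the log2 scale. They were 1.229 (0.0367) for Irf1, 1.034 (0.0388) for Jak2, 1.405 (0.0169) for Nrp2 and 1.297 (0.0388) for Ptger4. Cd3g, Jak2 and Ptger4 fall outside the rule for named genes and were chosen after their values were seen. Without the block limma called 0 genes (smallest adjusted p = 0.267, 52 unadjusted), and with the block and re-centring together it called 0 (smallest adjusted p = 0.0954). Re-centring took the median interaction of all genes from 0.36 to 0.03 and of the 9 genes from 1.371 (median SE 0.292) to 1.041 (0.285), with Il21r at 1.864 ± 0.355 and Cd3e at 1.311 ± 0.296. The calls ended with smaller differences and also with fewer small p values for the adjustment, as 54 genes against 117 had an unadjusted p under 0.05, and the part of each was not tested. Among the 10 splits of the 6 mice into 2 groups of 3, 1 gave 9 or more genes with the block, the real one, and the highest other gave 1. Without the block 10 of 10 gave 0 or more, with a real value of 0 and a highest other of 0. The splits are too few for a share under 0.05.

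Ikbkb, a kinase gene of NF-kB signalling, was higher in CD34- cells in the 3 high-fat pairs and lower in the 3 low-fat pairs, with a difference between diets of 1.346 ± 0.345 on the log2 scale. This sign pattern was not tested as such, and the interaction had an adjusted p of 0.334. Among 75 named genes 1 showed it, where a chance of 3.125% per gene gives 2.34, and among 23 lists 0 did. The named genes were mostly chosen for their differences, so that chance need not hold for them. Among all 594 genes kept, 20 showed the pattern.

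On the high-fat diet, limma called 14 of 20 T and NK cell genes and 2 of 5 B cell genes higher in CD34- than in CD34+ cells. On the low-fat diet it called 8 of 20 and 0 of 5 (9 and 2 unadjusted). With the mouse as a block, 19 and 4 were higher on the high-fat diet and 14 and 3 on the low-fat diet. The list calls were lost at an estimated correlation (camera adjusted p = 0.235 and 0.355 on the high-fat diet, and 0.347 and 0.42 on the low-fat diet). A lower share of myeloid cells in CD34- samples that raised all other cell types alike would raise fibroblast genes too. The T and NK median lay above the fibroblast median by 2.799 ± 0.543 (low-fat) and 4.008 ± 0.387 (high-fat). Here ± is an SE from the spread over the genes of the lists, which are not independent, and not over samples. The gap argues against such an even rise only. It cannot decide on a lower share of myeloid cells as such, which need not raise fibroblast genes. Depth as the cause is argued against by the pairs, since the lowest median of the list over the pairs was 1.053 and CD34- was the deeper library in some pairs and the shallower in others. T and B cells among the sorted CD34- cells, which a gate on CD11b would mostly remove, stay open. Cd3d, Cd3e, Cd3g, Cd6 and Ms4a1 had a median above 0 in 6 of 6 pairs, with Cd3e at 9.46 ± 0.82 (SD, n = 3) in high-fat CD34- samples. These genes belong to the lists of the pattern and so cannot decide. The remark on the gate covers T and B cells only. NK cells in CD34- samples also stay open and were not tested, although Ncr1, a receptor gene of NK cells, was higher on both diets. A difference between the populations themselves stays open and was not tested.

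Matrix genes were high in high-fat CD34+ replicate 2. The scale of that library as the cause is argued against, since the collagen and matrix lists exceeded the other libraries of the group by 1.81 more than all genes did. A difference of the mouse that raised fibroblast markers alike in both its populations is argued against too. In its CD34- sample the markers exceeded the other samples of that group by a median of 0.1421 ± 0.375 (SD over markers) and at most by 0.28. In its CD34+ sample the median excess was 2.496. These values cannot decide on a difference of that mouse confined to its CD34+ cells. Stromal cells in that library, which the gate on CD45 would remove, stay open: Col1a2 stood at 11.2 on the log2 scale and 9 of 9 fibroblast markers were highest there, but 7 of them belong to the collagen and matrix lists, and the other 2, Acta2 and Cxcl12, exceeded the other libraries by a median of 0.8077, too few to decide. No biological explanation was tested, because the design sets this sample in no group of its own.

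All 30 genes called for diet in CD34- cells were higher on the high-fat diet. RNA of fat cells carried into the sort would bring Adipoq along. Adipoq changed by 0.99 ± 0.64 in CD34- cells and by -1.10 ± 0.64 in CD34+ cells. Its log2 change lay 1.76 ± 0.77 below that of Fabp4 in CD34- cells and 2.98 ± 0.77 below in CD34+ cells. Adipoq reached at most 3.605% of Fabp4 in a high-fat library, a ratio of 2 probes after amplification. Fabp4 thus rose more than Adipoq, but such RNA cannot be excluded, as macrophages express Fabp4 too. Normalization was weighed by re-centring, after which the median change of the 30 genes was 1.506 against 1.822 before, with a median SE of 0.413. All 30 stayed higher, but they were picked for their rise, and the median of all genes moved only from 0.35 to 0.03. These 30 genes therefore cannot decide. Over all genes, 17 higher and 0 lower passed with re-centring, and 12 higher and 1 lower with quantile normalization. The calls stayed nearly all higher, while their number depended on the scaling. A larger share of macrophages cannot be told apart from a change within the cells, as genes outside the macrophage list exceeded the macrophage marker with the largest change by a median of 0.2153, less than its SE of 0.390. Cd34 itself differed by 1.42 between the diets in CD34- cells and did not pass (limma adjusted p = 0.104). Whether the sort parted the populations equally well on both diets was not tested. The low-fat CD34- samples also enter the population comparison on that diet, so the comparisons are not independent. An effect of the diet itself, which the design names, stays open.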

How the results depend on the processing

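Voom, the filter on recovered counts, the 2 libraries left out together (high-fat CD34+ replicate 2 and low-fat CD34- replicate 3) and the mouse block with re-centring were chosen after the results were seen. Over all alternatives, named genes that had passed kept direction and side in 1770 cases, fell short in 568 and reversed in 0. Those that had not passed stayed so in 2092 cases, passed in 222 and reversed in 26. Called lists kept their call in 752 cases and lost it in 119, 39 of these with an estimated correlation. The count of genes stayed within 1.5 times the reported one in the 4 comparisons with pseudocounts of 10 and 20, without the filter, with either other filter and with values under 20 set to 20. Where no cause is given below, the cause was not tested. Low counts limit Cd34, Timp1, Col4a2 and Igf1, and a log2 change of 1 was recovered in 50.4% of simulated genes for diet in CD34- cells.

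For CD34- against CD34+ cells on the high-fat diet, 53 genes became 35 without the trend, 96 with sample weights, 142 with a random and 149 with a fixed mouse block, 141 with the block and re-centring, 126 and 3 by the plain test unadjusted and adjusted, and 91 with the 2 libraries out. On the low-fat diet, 58 became 116 with weights, 131 and 149 with the blocks, 139 with the block and re-centring, and 109 and 0 by the plain test; the 8 lists became 5 with values under 20 set to 20. For diet in CD34+ cells, 14 genes became 7 with quantile normalization, 0 without the trend, 0 with only the 6 samples compared, 32 with the replicate number as a block, 65 and 0 by the plain test and 54 with the 2 libraries out, where 10 lists became 6. For diet in CD34- cells, 30 genes became 17 with re-centring, 13 with quantile normalization, 17 with voom, 210 with weights, 55 with the replicate number as a block, 135 and 2 by the plain test and 49 with the 2 libraries out. The interaction went from 0 genes by limma (52 unadjusted) to 2 with weights, 7 and 9 with the blocks, 57 by the unadjusted plain test and 1 with the 2 libraries out. Weights ran from 0.270 to 4.98, and their estimate stopped before it converged. With an estimated correlation 0, 0, 0 and 0 lists passed by camera.

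With one replicate left out, counts of genes ran from 0 to 64 (high-fat), 26 to 56 (low-fat), 0 to 29 (CD34+), 4 to 31 (CD34-) and 0 to 0 (interaction), and lists from 9 to 11, 5 to 11, 7 to 11 and 7 to 12. A group left with 2 samples was assumed to vary like the others. Fewer samples were compared in these fits.

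Cd34 on the low-fat diet (-1.68) missed the threshold at -1.17 and -0.91 with pseudocounts of 10 and 20, -1.68 without the filter, where more genes were tested, -1.18 with values under 20 set to 20, -1.63 with re-centring, -1.24 with quantile normalization, -1.52 with voom, -1.68 with only the 6 samples, -1.68 by the adjusted plain test and -1.18 with the 2 libraries out (adjusted p 0.0519 to 0.254 over these), and ran from -1.96 to -1.18 with one replicate left out. With the fixed mouse block Cd34 passed on the low-fat diet (limma adjusted p = 0.0155). On the high-fat diet it reversed to 0.073 with the 2 libraries out and ran from -0.59 to 0.073.

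Reversed genes had not passed. Ndufb6 for diet in CD34- cells became -0.078 with re-centring. Quantile normalization gave -0.0021 for Egr1 (high-fat), 0.049 for Ccr2 (low-fat), -0.029 for Ndufb8 and -0.35 for Ptprc (diet, CD34+), and -0.0091 for Cycs, -0.10 for H2-D1 and -0.16 for Ndufb6 (diet, CD34-). With one replicate left out, Hsp90aa1 ran from -0.36 to 0.020, Cd34 from -0.33 to 0.34, Ptprc from -0.088 to 0.10 and Ccr2 from -0.60 to 0.39 for diet in CD34+ cells, Fcgr4 from -0.38 to 0.16, Jun from -1.10 to 0.13 and Ccr2 from -0.59 to 0.40 on the low-fat diet, and Egr1 from -0.15 to 0.58 and Cdkn1a from -0.63 to 0.12 on the high-fat diet. With the 2 libraries out, Jun became 0.13, Cd34 -0.33 and Ptprc -0.0102. Rescaling on the panel's reference genes was not run, as these genes were not analysed here, and the stricter filter removed Cd34 from the test.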

Other observations

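The values of the population and diet comparisons below use tests chosen before the data were examined. Leaving out each replicate in turn was also planned, but the fit without high-fat CD34+ replicate 2 was picked for this part after results were seen.

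Genes of mitochondrial oxidative phosphorylation were not called by camera in any of the 4 comparisons. The medians of the 10 tested genes were -0.04 and 0.00 for CD34- against CD34+ cells on the high-fat and low-fat diets (adjusted p = 0.416 and 0.57) and 0.03 for diet in each population (0.68 in CD34+ and 0.152 in CD34- cells). TGF-beta and BMP signalling genes, a main theme of the panel, had medians of 0.21, -0.01, -0.10 and 0.43 over 10 genes in the same order (0.476, 0.57, 0.68 and 0.389). Of these, Smad3, which encodes a signal carrier of the pathway, was higher in CD34- cells on the high-fat diet by 1.27 ± 0.37 (limma adjusted p = 0.0479). With the mouse as a block Smad3 (adjusted p = 0.00165), the receptor gene Tgfbr2 (1.25 ± 0.21, 0.000387) and Ski (0.64 ± 0.22, 0.0453) were higher there, where Tgfbr2 and Ski were named after their values were seen, and on the low-fat diet Smad3 was higher (0.73 ± 0.26, 0.0487) and Smurf1 lower (-1.06 ± 0.33, 0.0273). Without high-fat CD34+ replicate 2 and without the block, Smad3 was at 1.315 on the high-fat diet (0.059) and Tgfb1 at 0.980 for diet in CD34+ cells (0.0468). The interferon list of 12 genes was split for diet in CD34+ cells, where Oasl1 rose and Irf1 fell, with a median of -0.29 (0.406), and 3 rose and 1 fell without high-fat CD34+ replicate 2 (median -0.33, 0.906). In CD34- cells Oasl1 differed by 3.04 ± 0.84 between the diets (adjusted p = 0.054), and the interferon median was -0.02 (0.281).

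The counts of genes and lists were compared with those from other splits of the same samples. For CD34- against CD34+ cells, among the 4 splits that part the 3 same-numbered pairs of a diet, 1 gave as many genes as the real 53 on the high-fat diet and 1 as many as the real 58 on the low-fat diet, with a highest other of 0 in each. For lists, 1 of 4 gave the real 11 on the high-fat diet (highest other 7) and 1 of 4 the real 8 on the low-fat diet (highest other 5). The 10 splits of the 6 samples of a diet comparison included 1 with the real 14 genes in CD34+ cells and 1 with the real 30 in CD34- cells, with a highest other of 0 in each. They included 1 with the real 10 lists in CD34+ cells (highest other 5) and 1 with the real 10 in CD34- cells (highest other 6). The splits are too few for a share under 0.05.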
